A study of Homo sapiens with 4 samples.

How the data were processed

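Total RNA of the culture supernatant was sequenced from 4 libraries, 2 of EPN24-Cas13d and 2 of EPN24. Per the labels' protocols, the supernatant was cleared by centrifugation and filtration, ERCC spike-in RNA was added to 200 µl of it before extraction, and libraries were made with 17 PCR cycles and sequenced as 150-nt read pairs. The labels name no molecular identifiers. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, STAR 2.7.10a, featureCounts 2.0.1 of Subread and DESeq2 1.36.0, with hg38 and GRCh38 as builds. The annotation release, the strand setting and the multi-mapping option are not given in the sources used here.

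The authors deposited a table of expected counts per gene, that is read counts with fractions, in which 7.83% to 9.20% of values per library were not whole. How the fractions arose was not tested. Among whole values above 0, 66.8% to 72.4% were even for genes and 94.4% to 98.4% for ERCC transcripts, as when both mates of a pair are counted. No normalization had been applied to these deposited counts. The table held 61640 rows, of which 5 were left out: all are pieces of a single gene's row, broken over several lines with 6 values after the length in place of 4. The remaining 61543 genes and 92 ERCC transcripts were used. A second deposited table holds the authors' DESeq2 results: a mean normalized count (signal), log2 fold change and its standard error, a Wald statistic (score), and p-values. Its design and size factors are not given in the sources used here. The deposited gene length in bp, an exon length (other unit), came with the counts. All gene symbols of tested genes came from the authors' table. A gene of a single strand can carry reads of its antisense or overlapping partner, since the strand setting is unknown, and no such pair was resolved.

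Counts were rounded and tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (20476 of 61543), scaled by TMM without the ERCC rows, and tested with the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The approximate SE is the absolute log2 fold change divided by the square root of F. CPM values carry the TMM scaling, and the ± values are SDs of the 2 libraries. Totals per library were 5097332 and 4863449 gene counts in EPN24-Cas13d and 1830860 and 1903492 in EPN24. The replicates of a group hold different values, with a chi-square per degree of freedom of 2.47 over 13061 genes in EPN24-Cas13d and 3.56 over 17677 genes in EPN24, or 1.24 and 1.78 with counts halved. Mates counted separately and PCR copies raise these values, so they do not show separate cultures, and each library was used as labelled. Across 27 ERCC transcripts of at least 50 counts in every library, the log2 ratio between groups had an SD of 0.34.

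The groups were taken from the sample titles, and the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes are named as the 8 largest and 8 most negative log2 fold changes among genes past the threshold with a symbol, no overlap between groups and a mean of at least 20 CPM, leaving out pseudogenes and clone-style symbols, plus the 2 members with the smallest p of each list with at least 5 tested members and the 2 most abundant members of shorter lists. The 22 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for the 21 with at least 5 tested members, and again with an estimated correlation. With ERCC scaling the self-contained fry test was used. Group differences in single values were tested by exact permutation, two-sided. GC content is that of the longest GENCODE transcript of each gene ID in build 38, found for 97.3% of tested genes. Coordinates are those of the deposited table.

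Alternatives covered DESeq2 size factors, total counts, ERCC totals, no filter and a filter of at least 10 counts and 10 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block, each library left out, and a length trend removed. Counts halved, a GC trend removed and background subtracted at the olfactory receptor density were added after seeing the data. On simulated counts for 20476 genes with 200 changed, the test recovered 35.0% of 2-fold and 82.0% of 4-fold changes, with 18 false calls. The simulated changes went evenly up and down from a shared mean profile. The simulation therefore does not cover a comparison in which most genes differ.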

Results

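RNA was measured in the culture supernatant of HEK293T, a human embryonic kidney cell line, that released EPN24 nanocages, protein shells carried out of the cell. Total RNA of the supernatant was sequenced, so RNA inside the shells is not told apart from other RNA. In 1 group EPN24 was fused to Cas13d, an RNA-guided CRISPR protein that binds RNA, and in the other EPN24 was used alone, with 2 libraries in each group. The comparison asks which cellular RNAs leave the cell with the nanocage when Cas13d is attached. The 2 EPN24-Cas13d libraries held 5097332 and 4863449 gene counts, and the 2 EPN24 libraries held 1830860 and 1903492. On the TMM-scaled CPM used below, a floor of 3 counts per library corresponded to 0.721 and 0.755 in the EPN24-Cas13d libraries and to 1.34 and 1.42 in the EPN24 libraries. Floors and intervals cover counting error only, since PCR copies without molecular identifiers are not independent molecules. Most whole counts were even, as when both mates of a pair are counted, so single counts may not be independent either. The bounds given against a floor may therefore be too high and the intervals too narrow. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. A cell lysate or a supernatant without nanocages was not analysed here.

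EPN24-Cas13d supernatant carried far more cellular RNA for the same amount of synthetic ERCC RNA, and this RNA was mostly messenger RNA. Gene counts per ERCC count were 58.1 ± 1.68 (SD, n = 2) with Cas13d and 3.95 ± 0.231 (SD, n = 2) without it, a 14.7-fold difference. An exact permutation test, two-sided, gave p = 0.333, the smallest p that 2 against 2 libraries allow. ERCC transcripts took 1.73% and 1.66% of all counts in the EPN24-Cas13d libraries, and 19.6% and 20.9% in the EPN24 libraries. Protein-coding genes made up 93.8 ± 0.257% of gene counts with Cas13d and 40.8 ± 2.28% without (SD, n = 2). The RN7SL family, the RNA scaffold of the signal recognition particle with its near-identical copies, showed the opposite, 1.62 ± 0.173% with Cas13d and 36.4 ± 2.31% without. That sum leaves out ENSG00000282885, an annotated lncRNA that shares the reads of RN7SL2. It took a mean of 0.509% with Cas13d and 12.8% without, so the share of counts on RN7SL sequence may be higher. Annotated lncRNA genes took 3.40 ± 0.0661% and 18.8 ± 0.216%, or 2.86 ± 0.00235% and 5.35 ± 0.574% without ENSG00000282885 and ENSG00000259001, which share the reads of RN7SL2 and RPPH1, an exclusion chosen after the data were seen. Mitochondrially encoded RNAs took 0.0261 ± 0.00224% with Cas13d and 0.317 ± 0.0389% without. Per ERCC count the ratio of EPN24-Cas13d to EPN24 was 33.8 for protein-coding genes, 2.66 for lncRNA genes (7.84 without those 2 loci), 1.20 for mitochondrial RNAs, 0.701 for snRNAs and 0.657 for the RN7SL family. Each class share named here had an exact permutation p of 0.333, again the smallest possible. Each library's own 10 most abundant genes held 52.6 ± 2.85% of gene counts in EPN24 and 5.93 ± 0.249% in EPN24-Cas13d, and without the 10 genes of highest mean share over the 4 libraries, led by RN7SL1, the protein-coding difference was 14.3 in place of 53.0 percentage points.

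**Figure D1:**
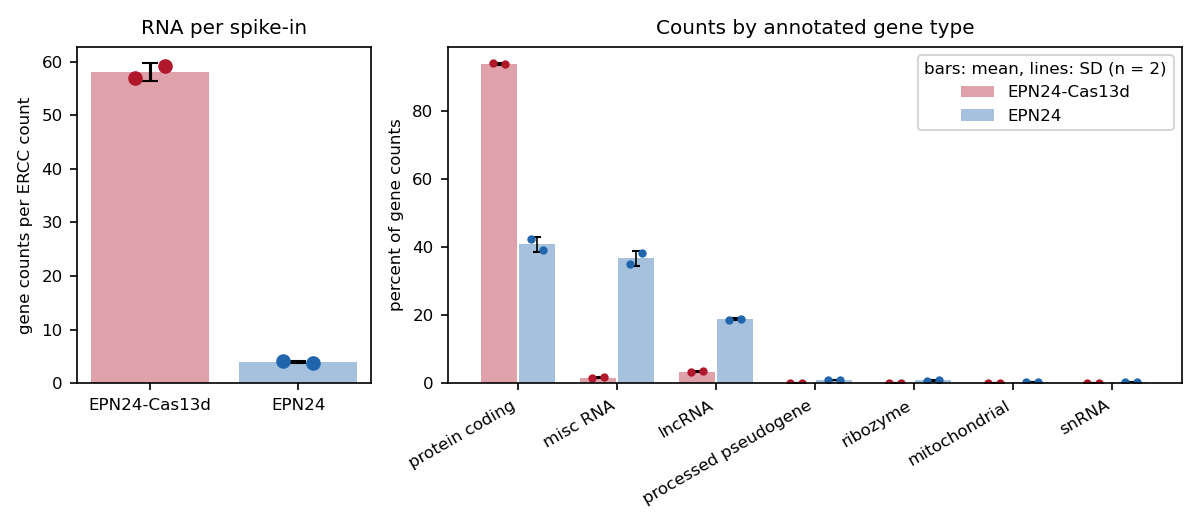
Left, gene counts per ERCC count in each library (points), with the group mean (bar) and SD (line, n = 2): the EPN24-Cas13d libraries lie at 56.9 and 59.3 and the EPN24 libraries at 4.11 and 3.79. Right, percent of gene counts by annotated gene type, where protein-coding genes take 93.8% in EPN24-Cas13d and 40.8% in EPN24.

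Most tested genes differed between the groups. CBX6, a Polycomb chromobox protein (ENSG00000183741.12, chromosome 22, 38861422 to 38872249 on the minus strand), measured 2965 ± 70.9 against 34.7 ± 12.5 CPM (SD, n = 2 in each group), a log2 fold change of 6.42 with an approximate SE of 0.16. SESN2, a stress-induced sestrin (ENSG00000130766.5, chromosome 1, 28259518 to 28282491 on the plus strand), measured 3708 ± 11.5 against 47.5 ± 2.87 CPM, a log2 fold change of 6.28, SE 0.12. SLC7A5, a large neutral amino acid transporter, measured 2228 ± 23.9 against 31.2 ± 11.4 CPM and had a log2 fold change of 6.16. The transcription factor KLF16 (6.35), the zinc finger genes ZNF853 (6.10) and ZNF414 (5.98), the cysteine string protein gene DNAJC5 (6.09) and the scavenger receptor gene SCARF2 (6.09) completed the 8 largest increases. EEF2, elongation factor 2 (ENSG00000167658.16, chromosome 19, 3976056 to 3985463 on the minus strand), was the most abundant gene in EPN24-Cas13d, with 18420.3 ± 272 against 887 ± 58.8 CPM and a log2 fold change of 4.38. In the other direction FBXO5, an inhibitor of the anaphase-promoting complex (ENSG00000112029.10, chromosome 6, 152970519 to 152983579 on the minus strand), measured 0.366 ± 0.162 against 57.3 ± 14.1 CPM, a log2 fold change of -7.13, SE 0.47. The histone chaperone gene ANP32E (-6.62), the nucleosome-binding gene HMGN5 (-5.43), the transcription repressor gene ZEB1 (-5.32), the BCL2-family gene PMAIP1 (-5.28), the lncRNA THAP9-AS1 (-5.52) and the snRNAs RNU11 (-6.71) and RNU4-1 (-6.17) were also lower. All 16 had adjusted p between 3.47e-13 and 1.68e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and with ERCC scaling each remained on its side, the 8 decreases at log2 fold changes from -3.86 to -1.94. FBXO5 and ANP32E lay under the floor in both EPN24-Cas13d libraries, and the 3 counts of FBXO5 against 248 give a log2 ratio of -7.27 (95% exact binomial interval -9.56 to -5.71). HMGN5 had 13 and 0 counts in EPN24-Cas13d: without replicate 2 its log2 fold change was -4.41, and without replicate 1 it was at least 93.4-fold lower against the floor of 3 counts. With the GC trend removed, a setting chosen after the data were seen, the 8 increases lay between 3.12 (SCARF2) and 4.98 (CBX6), and 6 of the 8 decreases moved by more than 1.5 times, HMGN5 to -2.82. With the stricter filter the increases lay between 4.79 and 5.22 and the decreases between -8.30 and -6.47. Background subtraction moved 5 of the 8 increases and 8 of the 8 decreases by more than 1.5 times, and in these 3 settings all 16 were called on the same side.

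**Figure D2:**
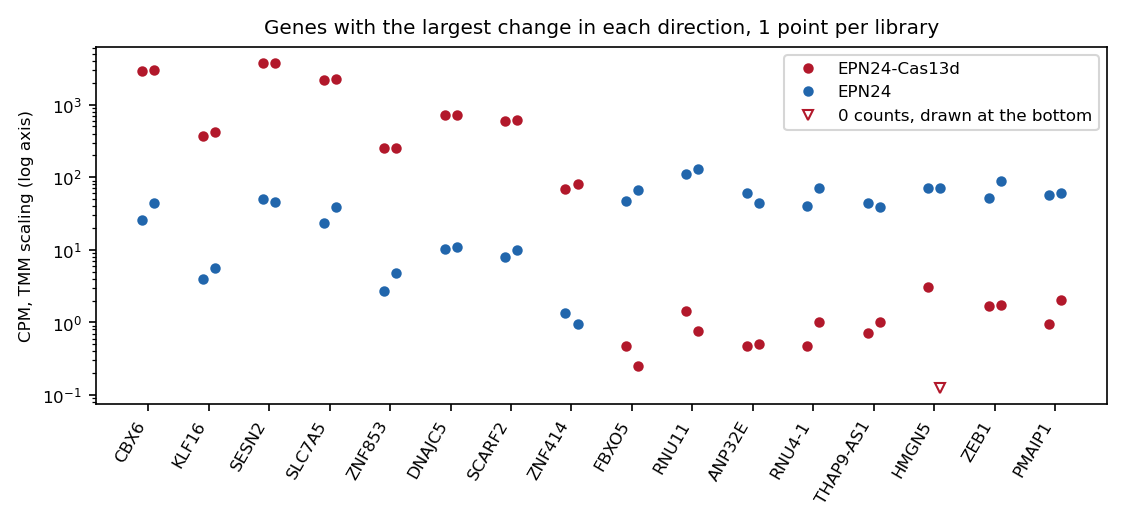
CPM per library with TMM scaling, on a log axis, for the 8 genes with the largest log2 fold change in each direction. Points of EPN24-Cas13d lie above those of EPN24 for CBX6 to ZNF414 and below them for FBXO5 to PMAIP1, and 1 EPN24-Cas13d library had 0 counts for HMGN5.

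Of 20476 tested genes, 16556 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6685 higher and 9871 lower in EPN24-Cas13d, and 15830 of them differed by a log2 fold change of at least 1. The stricter filter, of at least 10 counts and 10 CPM, called 8014 of 10051 genes, 4035 higher and 3979 lower, 6914 of them by at least 1. Background subtraction, chosen after the data were seen, called 5320 higher and 5775 lower. The TMM counts compare each gene's share of the sample after TMM scaling, which centres the libraries on one another. Scaling to ERCC totals instead, which compares RNA per volume of supernatant, moved the median log2 fold change of all tested genes up by 3.34, from -0.96 to 2.38. It called 12437 genes, 11960 higher and 477 lower, so 96.2% of calls were higher against 40.4%. All 6685 genes higher with TMM were also higher with ERCC scaling, while of the 9871 lower ones 477 were lower, 7810 were not called and 1584 were higher. Of 370 olfactory receptor genes, a family known mainly from the nose, 84.6% had a count in an EPN24 library and 26.2% in an EPN24-Cas13d library, at 1.63 and 0.158 counts per kb. Of the 9871 lower genes, 5762 (58.4%) lay within 3 times that density in EPN24.

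Among the gene lists, glycolysis, cytosolic chaperone and integrated stress response messages were higher in EPN24-Cas13d relative to other genes. Of 18 glycolysis messages 15 were higher and 3 lower, with a median log2 fold change of 2.42: PKM, pyruvate kinase, measured 2062 ± 24.9 against 153 ± 21.4 CPM (3.75), and ALDOA, aldolase, 829 ± 24.2 against 105 ± 8.9 CPM (2.98). Of 20 chaperone messages 17 were higher and 3 lower (median 1.87), with HSPA8, the constitutive HSP70, at 1598 ± 56.2 against 133 ± 16 CPM (3.59) and CCT7, a subunit of the chaperonin that folds actin and tubulin, at 894 ± 5.91 against 79.5 ± 6.72 CPM (3.49). Of 19 integrated stress response messages 12 were higher, 2 lower and 5 not called (median 1.55): besides SESN2, DDIT4, an inhibitor of mTORC1 signalling, measured 659 ± 18.5 against 28.4 ± 4.0 CPM (4.53). HSP90AA1, a stress-responsive HSP90 chosen after its values were seen, was lower (-1.28), turning to 2.07 with ERCC scaling. Without EPN24-Cas13d replicate 1 and replicate 2, 0 and 1 glycolysis messages were lower, and without EPN24-Cas13d replicate 2 or EPN24 replicate 2, 1 stress response message was lower. The camera test with Benjamini-Hochberg adjustment gave adjusted p = 2.07e-06, 2.07e-06 and 1.41e-05 for the 3 lists at a preset correlation. None passed with an estimated correlation, where the adjusted p was 0.389, 0.434 and 0.389. That version rests on the few residual degrees of freedom of 4 libraries and could hardly call any list. With ERCC scaling the list medians were 5.79, 5.24 and 4.91. Camera compares a list with all other tested genes, many of them near the olfactory receptor density in EPN24. With the stricter filter the median log2 fold change of all tested genes was 0.049 in place of -0.96. Genes tested in both settings moved by a median of -1.20. Camera was not run with that filter or with background subtracted, so how far these and later list calls depend on the sparse genes is not known. Of the 29 higher genes named as examples by rule for this and later lists, 21 moved by more than 1.5 times with the GC trend removed, 29 with the stricter filter and 27 with background subtracted. Of the 15 lower ones 9, 12 of 12 tested and 10 of 13 tested did. In these settings IRF7 and PTPRC (GC trend removed) and TF (background subtracted) were not called, and PTPRC, FGB or AHSP were not tested in some. For this and every list below, the counts adjusted over the list alone were the same as those over all genes tested.

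Mitochondrial messages, small structured RNAs, snRNAs and histone messages were lower relative to other genes. All 13 mitochondrially encoded messages were lower (median log2 fold change -2.97, but 0.37 with ERCC scaling, where 3 were called higher): MT-CO1 measured 22.0 ± 2.59 against 317 ± 18.5 CPM (-3.85, or -0.50 and not called with ERCC scaling) and MT-ND5 51.1 ± 2.86 against 356 ± 9.7 CPM (-2.80, turning to 0.56 with ERCC scaling). All 9 tested small structured RNAs were lower (median -4.05, -4.01 with the member at 0 set to its bound, and -0.68 with ERCC scaling, where 5 of them were still lower): RPPH1, the RNA of RNase P (ENSG00000277209.1, chromosome 14, 20343075 to 20343407 on the minus strand), measured 301 ± 3.26 against 5523 ± 865 CPM and RN7SL2 (ENSG00000274012.1, chromosome 14, 49862550 to 49862849 on the minus strand) 6229 ± 779 against 110330 ± 13966 CPM. Both share reads with overlapping or near-identical loci, and RMRP is in that count under 2 identifiers with identical counts, so these values are uncertain. All 8 tested spliceosomal snRNAs were lower (median -5.36, -4.65 at the bound, -2.07 with ERCC scaling), with RNU11 of the minor spliceosome at 1.10 ± 0.486 against 120.2 ± 15.5 CPM and RNU4-2 at 2.23 ± 1.12 against 80.5 ± 5.34 CPM. With ERCC scaling 4 snRNAs were called lower, and the snRNA at 0 counts entered that median at its fitted value, not at a bound. Of 43 tested replication-dependent histone messages 28 were lower, 7 higher and 8 not called (median -1.39, turning to 1.98 with ERCC scaling): H2BC18 measured 26.4 ± 2.6 against 281 ± 8.28 CPM (-3.42, or -0.058 and not called with ERCC scaling), while H1-4, a linker histone, measured 3981 ± 516 against 646 ± 9.18 CPM (2.62). Near-identical histone genes can share reads. Of 78 cytosolic ribosomal protein messages 43 were lower, 23 higher and 12 not called (median -0.54, turning to 2.83 with ERCC scaling), and this median lay above the -0.96 of all tested genes although camera's direction was down. RPS3 (2834 ± 75 against 344 ± 18.1 CPM, 3.04) and RPL3 (4545 ± 211 against 507 ± 36.3 CPM, 3.16) were higher, and RPL38 (-3.94, or -0.58 with ERCC scaling), chosen after its values were seen, was lower. The camera test with Benjamini-Hochberg adjustment gave adjusted p = 6.27e-10 for mitochondrial, 5.51e-13 for small structured, 0.00129 for snRNA, 1.00e-04 for histone and 0.0348 for ribosomal protein RNAs. With an estimated correlation, where few residual degrees of freedom again left little power, none passed, at adjusted p = 0.406, 0.389, 0.434, 0.475 and 0.733. The ribosomal protein call was also lost without EPN24-Cas13d replicate 1 or replicate 2 (adjusted p = 0.215 and 0.175) and turned the other way without a filter (adjusted p = 0.264), where the histone and snRNA lists did not pass either (adjusted p = 0.252 and 0.0547). Without EPN24-Cas13d replicate 2, 4 histone messages were higher, and without EPN24 replicate 1 the snRNA median was -6.21.

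**Figure D3:**
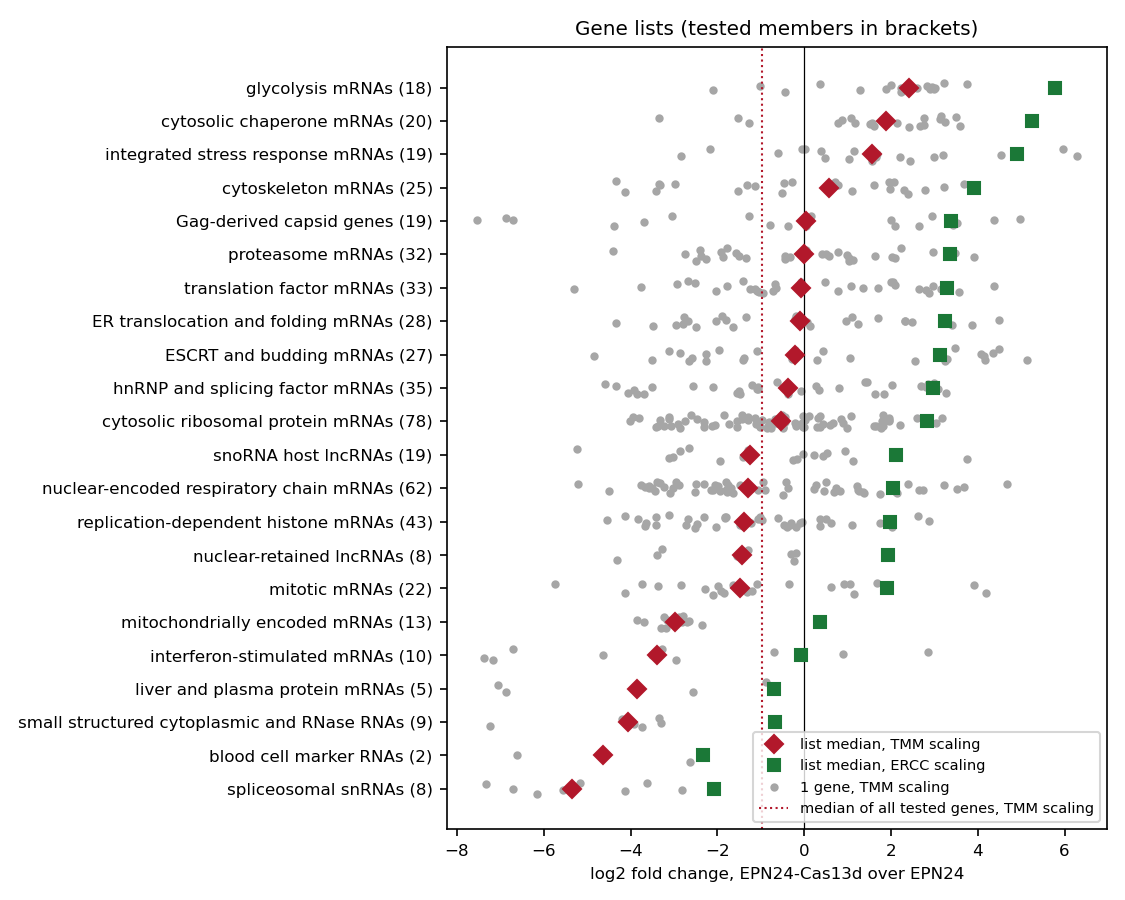
Log2 fold change of EPN24-Cas13d over EPN24 (horizontal axis) for each gene list, with 1 grey point per gene under TMM scaling, diamonds for list medians under TMM scaling and squares for list medians under ERCC scaling. Glycolysis has the highest median (2.42, 5.79 with ERCC scaling) and snRNAs the lowest with TMM scaling (-5.36, -2.07 with ERCC scaling), and the mitochondrial, histone and ribosomal protein medians are negative with TMM and positive with ERCC scaling.

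The other 13 lists with a test did not pass it by camera with Benjamini-Hochberg adjustment, and within most of them members went both ways. Nuclear-retained lncRNAs had 5 lower and 3 not called of 8 (median -1.43, turning to 1.92 with ERCC scaling, adjusted p = 0.0845), with FTX at 5.65 ± 0.164 against 54.9 ± 2.64 CPM (-3.27, or 0.084 and not called with ERCC scaling) and MEG3 at 1.49 ± 0.744 against 30.1 ± 10.4 CPM (-4.31, or -1.01 and not called with ERCC scaling). Of the 19 snoRNA host lncRNAs 5 were higher and 9 lower (adjusted p = 0.506), SNHG7 at 3.74 and SNHG6 at -5.24, or 7.10 and -1.93 with ERCC scaling. Without EPN24-Cas13d replicate 1, replicate 2 or EPN24 replicate 1, 3, 2 and 3 of these hosts were higher, and SNHG6 was at -6.32 and -4.56 without the former 2 libraries. ESCRT and budding messages, whose proteins cut vesicles from membranes, split 11 higher to 11 lower of 27 (adjusted p = 0.113), with CHMP1A (4.15) and VPS37B (4.49) higher. The Gag-derived capsid genes split 8 to 7 of 19 (adjusted p = 0.305), with RTL6 at 619.8 ± 7.62 against 19.7 ± 3.72 CPM (4.97) and RTL10 (4.38, or 4.99 without EPN24 replicate 1). Without EPN24 replicate 1 or replicate 2, 4 and 4 Gag-derived genes were lower. ER translocation and folding messages split 11 to 11 of 28 (adjusted p = 0.406), P4HB, a protein disulfide isomerase, at 4.49 and RPN1 at 3.88. Translation factors split 16 to 16 of 33 (adjusted p = 0.113), with EEF1G at 3.14 and EEF1A1, the most abundant messenger RNA in EPN24 and chosen after its values were seen, at -1.05, turning to 2.30 with ERCC scaling. Cytoskeleton messages split 12 to 10 of 25 (adjusted p = 0.113), with VIM, vimentin, at 3.69 and TUBA1B, an alpha tubulin, at 2.79. Proteasome messages split 15 to 12 of 32 (adjusted p = 0.595), with ADRM1 at 3.47 and PSMD3 at 3.92. Among nuclear-encoded respiratory chain messages 19 were higher and 35 lower of 62 (adjusted p = 0.587), with ATP5F1B at 3.67 and CYC1 at 4.68. Splicing factor messages split 13 to 19 of 35 (adjusted p = 0.760), U2AF2 at 3.26 and PRPF8 at 3.08, and mitotic messages 7 to 14 of 22 (adjusted p = 0.504), CDC20 at 3.92 and PLK1 at 4.19. In the ER, ESCRT and translation factor lists the median was slightly negative (-0.10, -0.20 and -0.082, or 3.25, 3.14 and 3.29 with ERCC scaling) although camera's direction was up. The mean was -0.12, 0.38 and 0.22. The means of the proteasome (-0.096), cytoskeleton (-0.065) and Gag-derived (-0.45) lists were negative while their medians (5.5e-04, 0.56 and 0.043) and camera's direction were positive. The ER and translation factor medians turned to 0.11 and 0.095 without EPN24-Cas13d replicate 2, and the ESCRT and translation factor medians to 0.11 and 0.16 without EPN24 replicate 2. The proteasome median turned to -0.018 without EPN24-Cas13d replicate 1 and -0.13 without EPN24 replicate 1, and the Gag-derived median ran from -0.20 without EPN24-Cas13d replicate 2, also negative (-0.075) without replicate 1, to 1.41 and 1.77 without EPN24 replicate 2 and replicate 1. Splicing factors had a median of -0.38, above that of all tested genes, with camera's direction down. The nuclear lncRNA list passed without EPN24 replicate 1 or replicate 2 (adjusted p = 0.0362 and 0.0407), and without a filter 7 of the 13 lists passed.

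Interferon-response messages and markers of blood and liver were mostly sparse, and those tested were mostly lower with TMM scaling. The filter works on CPM, so a sparse gene passed it with fewer counts in the smaller EPN24 libraries than in the EPN24-Cas13d libraries. Members tested only through EPN24, such as FGB and AHSP with 0 counts in EPN24-Cas13d, could only come out lower. The share of lower members in these lists therefore partly reflects the filter. Interferon-stimulated messages had 2 higher and 7 lower of 10 tested (median -3.39, -3.38 at the bound, -0.081 with ERCC scaling, camera adjusted p = 0.222 after Benjamini-Hochberg adjustment), with MX1 at 1.97 ± 0.064 against 19.5 ± 2.1 CPM (-3.28, or 0.045 and not called with ERCC scaling) and IRF7 at 21.7 ± 3.49 against 3.01 ± 1.1 CPM (2.84, or 0.47 with adjusted p = 0.381 once the GC trend was removed, a setting chosen after the data were seen). Without EPN24-Cas13d replicate 1, replicate 2 or EPN24 replicate 1, 1 interferon-stimulated message was higher, and without the last the median was -1.94. Of the liver and plasma protein messages 4 of 5 tested were lower (median -3.86, -3.66 at the bound, -0.69 with ERCC scaling, camera adjusted p = 0.238), and 2 were lower without EPN24 replicate 2. The liver median was -4.91, -6.58 and -2.97 without EPN24-Cas13d replicate 1, replicate 2 and EPN24 replicate 2. TF, transferrin, measured 4.26 ± 2.47 against 25.6 ± 4.77 CPM (-2.57, or 0.76 and not called with ERCC scaling). It was at -3.26 without EPN24-Cas13d replicate 1, and not called with background subtracted (-1.92, adjusted p = 0.0650). FGB, a fibrinogen chain, had 0 counts in EPN24-Cas13d and 5.35 ± 3.15 CPM in EPN24, at least 14.5-fold lower against a floor of 3 counts over the group. Only 2 of 12 blood cell markers were tested, so that list had no test. PTPRC, the leukocyte antigen CD45, measured 1.21 ± 1.0 against 7.82 ± 0.329 CPM (-2.64, or 0.68 and not called with ERCC scaling), or -3.78 and -1.93 without EPN24-Cas13d replicate 1 and replicate 2. It was not called by the DESeq2 Wald test (adjusted p = 0.0831) or with the GC trend removed (-0.77, adjusted p = 0.375). AHSP, an alpha-hemoglobin stabilising protein, had 0 counts in EPN24-Cas13d and 3.93 ± 1.14 CPM in EPN24, at least 10.6-fold lower. With a density of 16.2 counts per kb in EPN24, AHSP stood well above the 1.63 of the olfactory receptor genes. PTPRC (1.85), TF (2.15) and FGB (2.63) lay within 3 times that density, as did MX1, with 47 and 38 EPN24 counts over 17984 bp of exon. With ERCC scaling neither FGB (adjusted p = 0.0725) nor AHSP (adjusted p = 0.0930) was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and against the same floor their log2 bounds of EPN24 over EPN24-Cas13d were 0.44 and 0.027. Mates counted separately would lower these bounds, so they do not show either gene to be lower with that scaling. With 1 EPN24-Cas13d library left out the TMM bounds were at least 7.08-fold and 7.42-fold for FGB and 5.20-fold and 5.45-fold for AHSP. FGB was not tested without EPN24 replicate 2, nor AHSP without either EPN24 library.

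Genes with GC-rich transcripts were higher in EPN24-Cas13d and AT-rich ones lower. Across 19924 tested genes with a GC value, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.467, and 0.615 among genes of at least 10 CPM. From the lowest to the highest GC quintile, the median log2 fold change ran -2.85, -1.65, -0.52, 0.63 and 1.82, and with ERCC scaling 0.47, 1.69, 2.82, 3.97 and 5.16, so that the lower 3 medians turned positive. Each of the 4 pairs of 1 EPN24-Cas13d and 1 EPN24 library gave a rho between 0.459 and 0.476, while replicate 1 over replicate 2 gave -0.0803 in EPN24-Cas13d and -0.00218 in EPN24. Among the lists camera called at its preset correlation, the higher ones had a median GC of 53.2% (glycolysis), 51.7% (stress response) and 46.4% (chaperones), and the lower ones 44.3% (mitochondrial), 46.8% (snRNAs), 47.9% (ribosomal protein), 57.3% (histones) and 62.7% (small structured RNAs), against 49.5% for all tested genes. Exon length had little relation to the fold change over all tested genes (rho 0.0192), and a negative one among genes of at least 10 CPM (rho -0.244). With a library left out the length rho ran from -0.105 to 0.0678.

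**Figure D4:**
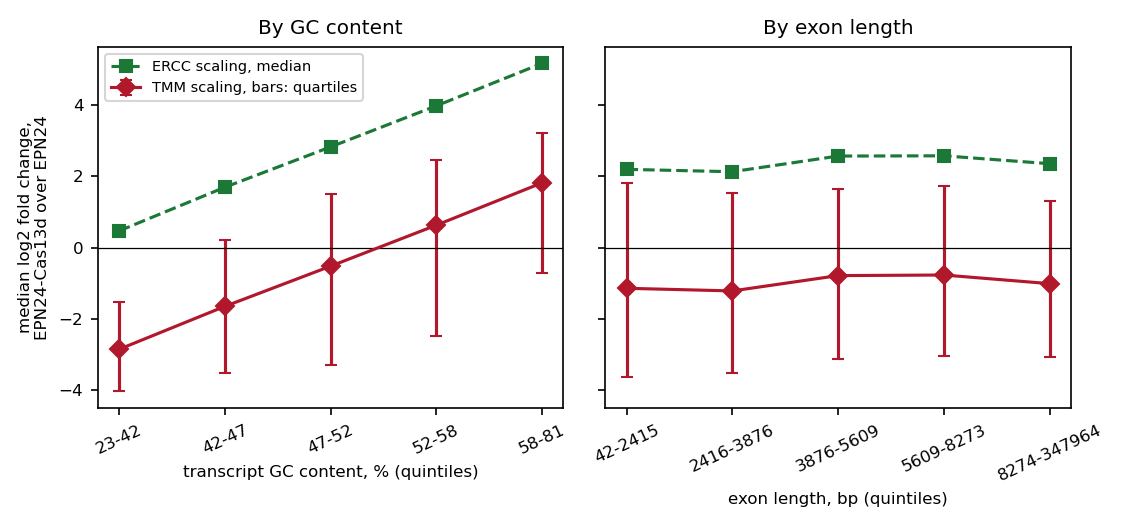
Median log2 fold change of EPN24-Cas13d over EPN24 (vertical axis) by quintile of transcript GC content in percent (left) and of exon length in bp (right). Diamonds show TMM scaling with bars at the quartiles, and squares show medians with ERCC scaling. With TMM scaling the median rises from -2.85 to 1.82 over the GC quintiles, and with ERCC scaling from 0.47 to 5.16.

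The authors' deposited table of the same comparison listed 53203 rows, 84 of them ERCC, and 12223 passed an adjusted p of 0.05, 12143 higher and 80 lower in EPN24-Cas13d. Its log2 fold changes ranked the 20476 genes tested here almost identically to the edgeR fit with TMM scaling (Spearman's rho 0.9999 across genes, which are not independent), and the edgeR values less the authors' had a median of -3.32. Of the 7844 genes called both in the authors' deposited table and by edgeR with TMM scaling, 6765 had the same sign and 1079 the opposite one. With ERCC scaling 11272 genes were called in both and 0 had opposite signs. A DESeq2 fit made here with ERCC size factors differed from the authors' deposited table by a median log2 of 0.02 over 9077 genes with a mean above 50. The authors' deposited table also lists 4596 genes with no count in any of the 4 libraries here, 4595 of them at a log2 fold change of 0, so which libraries it was computed from is not known. It is not taken as independent of these libraries.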

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

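The settings with counts halved, a GC trend removed or background subtracted, and protein-coding genes alone, were chosen after the data were seen. The stricter filter called 8014 of 10051 tested genes, 6914 of them with a log2 fold change of at least 1. The share of calls higher in EPN24-Cas13d, 40.4% with TMM scaling, was 96.2% with ERCC scaling and 50.3% with the stricter filter, both on the other side of an even split. It was 33.2% with total counts, 46.2% with the DESeq2 Wald test, 42.3% with the GC trend removed, 45.7% with counts halved, 47.9% with background subtracted, and 42.3% to 48.8% with a library left out. A fit with a library left out assumes that the lone library of its group varies like the others. The cause of these shifts was not tested.

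With the replicate number as a block (replicate block) 15041 genes were called, 43.5% of them higher, and the ribosomal protein list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.243). The block changed no other list's call and none of the 58 named genes' calls. As a check of pairing, the differences between replicates 1 and 2 had a correlation of 0.00300 between the groups over 9857 genes, so the numbers were not taken to pair the libraries.

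Of 8 lists called by camera with Benjamini-Hochberg adjustment, 0 passed with an estimated correlation: adjusted p was 0.406 for mitochondrial, 0.733 for ribosomal protein, 0.475 for histone, 0.434 for snRNA and chaperone, and 0.389 for small structured, glycolysis and stress response RNAs. The estimates for glycolysis (-0.030) and stress response (-0.054) lay below the preset 0.01, so a larger correlation did not end their calls. For the other called lists they ran from 0.205 (histone) to 0.445 (ribosomal protein). This version rests on the few residual degrees of freedom of 4 libraries. It could hardly call any list, so it does not decide whether correlation between members accounts for the calls. Fry with ERCC scaling and Benjamini-Hochberg adjustment called 19 lists, 17 as higher and 2 as lower. The lower ones were small structured RNAs (adjusted p = 0.00658) and snRNAs (0.00602). There the mitochondrial list did not pass (adjusted p = 0.296, direction up), the ribosomal protein (8.53e-04) and histone (0.00134) lists turned to higher, and ER (8.53e-04), proteasome (0.00124), ESCRT (7.36e-04), Gag-derived (0.00133), cytoskeleton (8.75e-04) and translation factor (8.53e-04) lists passed as higher. The nuclear lncRNA (0.00443), snoRNA host (7.36e-04), respiratory chain (0.00112), splicing factor (7.36e-04), mitotic (0.00309) and interferon-stimulated (0.0386) lists, down without passing in camera with TMM scaling, also passed fry as higher, and the liver list did not pass (0.358). Without a filter camera turned the ribosomal protein list the other way (adjusted p = 0.264), the histone (0.252) and snRNA (0.0547) lists did not pass, and ER (0.0202), proteasome (0.00480), ESCRT (0.0101), Gag-derived (0.0260), cytoskeleton (0.00252), translation factor (0.00841) and liver (0.0479) lists did. With a library left out the adjusted p ran from 1.19e-05 to 0.215 for the ribosomal protein list and from 0.0362 to 0.113 for the nuclear lncRNA list.

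Of 58 named genes, 48 kept their call with ERCC scaling, 1 was called on the other side, MT-ND5 (log2 fold change 0.56, adjusted p = 0.0204 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 9 were not called. Of those 9, FTX (0.084), MX1 (0.045), PTPRC (0.68) and TF (0.76) had a positive value. The protein-coding difference of 53.0 points was 14.3 without the 10 genes of highest mean share over the 4 libraries, led by RN7SL1. The GC relation (rho 0.467) was 0.615 at 10 CPM or more, 0.504 for protein-coding genes and 0.441 to 0.482 with a library left out. The length relation (0.0192) was -0.244, 5.33e-04 and -0.105 to 0.0678 in the same settings, and 0.0341 with background subtracted.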

Other observations

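Several gene families were grouped, and the genes named in this paragraph chosen, after their values were seen, so they describe these libraries only, and none passed camera with Benjamini-Hochberg adjustment (lowest adjusted p = 0.199). Of 16 protocadherin messages, which encode neuronal adhesion proteins, 12 were lower in EPN24-Cas13d and 1 higher (median log2 fold change -3.87, or -0.61 with ERCC scaling), with PCDH9 at 2.22 ± 0.42 against 62.9 ± 9.47 CPM. Of 54 collagen and laminin messages 34 were lower and 13 higher (median -2.46, turning to 0.85 with ERCC scaling), although LAMC1 (3.39), LAMA5 (2.49) and COL6A1 (2.58) were higher. Of 85 HOX, SOX and FOX messages 39 were higher and 22 lower (median 0.53), with FOXK1 at 1351 ± 26.1 against 37.0 ± 8.83 CPM and SOX12 at 589.6 ± 3.68 against 26.3 ± 4.35 CPM. Of 31 RNA polymerase subunit messages 15 were higher and 11 lower (median 0.96), POLR2A at 3.20. The 382 ZNF messages split 126 higher to 185 lower (median -1.19, turning to 2.16 with ERCC scaling). By annotated type, 29 of 36 tested miRNA genes were higher, but these short loci can lie inside longer host genes, and reads of a host cannot be separated from them here.

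All tests in this part were chosen after the data were seen, except the family densities and the correlation after background subtraction, which were fixed before those results were seen. Olfactory receptor genes had 1.63 counts per kb in EPN24 and 0.158 in EPN24-Cas13d. Blood and liver lists stood at 1.56 times the olfactory receptor density per kb in the higher EPN24 library. RNA of blood or liver cells from serum would bring their abundant transcripts, and ALB was at 2.33 and HBB at 0 counts per kb in EPN24. Human RNA of that kind is thus argued against as the main source. Reads were counted on human genes, so serum RNA of another species could go uncounted, and the test cannot decide about it. AHSP, at a mean of 16.2 counts per kb, stood at over 3 times each EPN24 library's own olfactory receptor density (1.83 in replicate 1 and 1.42 in replicate 2). APOH (13.5), ALAS2 (7.82) and TTR (6.43) did so in replicate 1 alone, and APOA2 (5.29), AFP (5.31), HBD (5.21) and HBM (4.39) in replicate 2 alone. TAS2R, KRTAP and DEFB genes, families known mainly from taste cells, hair and epithelia, stood at 1.71 times that density in the lower EPN24 library. In EPN24-Cas13d they stood at 0.485 against 0.158 counts per kb. Reads on such genes leave a background over gene bodies, such as genomic DNA, possible. The test set no upper limit, so it cannot tell a flat background from an uneven one. Olfactory receptor counts per ERCC count were 0.527 times as high in EPN24-Cas13d as in EPN24. This leaves possible a background of similar order in both groups, which would weigh more where there is less RNA. The range set for this test after the data were seen was wide, so it cannot tell an equal amount from a lower one in EPN24-Cas13d. After background subtraction 5312 of 9871 lower genes were still lower and 4203 were no longer tested, and 5243 of 6685 higher genes were still higher.

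The fold change rose with GC content, at a rho of 0.467. Flat background as the whole cause is argued against by a rho of 0.458 after its subtraction, and gene length by a rho of at least 0.418 within every length quintile. GC bias of library preparation as the whole cause cannot be told apart: 7 small structured RNAs of at least 55% GC had a median log2 fold change with ERCC scaling -5.72 from that of 4992 protein-coding genes of like GC, but they are another RNA class, so this gap does not decide about the messages. GC bias, the GC content of messages abundant in the cell and Cas13d's own preference stay open, and no lysate library was analysed here.

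Small structured and mitochondrial RNAs were lower with TMM scaling, at medians of -4.05 and -2.97. Their medians with ERCC scaling were -0.68 and 0.37, and the one farther from 0, -0.68, is consistent with an RNA pool of about equal amount per ERCC in both groups that was diluted by added messenger RNA. Against an exactly equal pool, 5 of the 9 small structured RNAs were still lower with ERCC scaling. The fry test with Benjamini-Hochberg adjustment also called that list lower there (adjusted p = 0.00658). The snRNA list had a median of -2.07 with ERCC scaling, with its member at 0 counts taken at the fitted value, and 4 of its 8 members were called lower. Fry with Benjamini-Hochberg adjustment called it lower (adjusted p = 0.00602). All 12 tested snRNA genes had a median of -1.49, and the class a ratio of 0.701 per ERCC count. How far snRNAs depart from an equal pool is thus uncertain. The 477 genes that edgeR called lower under both scalings are not covered by such a pool, but that count depends on the test. The authors' deposited DESeq2 results called 80 genes lower. Among the small RNAs named above, their Wald test did not call RPPH1 (adjusted p = 0.0579) or RNU4-2 (0.0663). It did call RN7SL2 (0.00575), RNU11 (8.6e-05) and RNU4-1 (0.0119) lower.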
